A study of Mus musculus with 48 samples.

How the data were processed

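RNA was measured in 48 samples of mixed gastrocnemius, a hindlimb muscle, from male C57BL6J mice. Each sample's labels carry their own glucose and insulin values, so each library was taken as 1 mouse; the labels do not state this. Per the labels' protocols, the mice drank water with 1% ethanol (vehicle) or with 100 ug/ml corticosterone for 2 weeks, and ate a control diet or the same diet with 571 mg/kg atglistatin, an inhibitor of adipose triglyceride lipase (ATGL, encoded by Pnpla2), the enzyme that starts the breakdown of stored triglyceride. Whether the corticosterone water also held ethanol is not recorded here, so ethanol could differ between the water treatments too. Corticosterone is the main glucocorticoid hormone of mice. Libraries were made with a QuantSeq kit, which primes at the 3′ end of polyadenylated RNA, and sequenced as 50 bp forward reads, per the labels' protocols. The values per gene therefore come from transcript ends and were not scaled by gene length.

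The deposited table holds raw counts, that is whole-number read counts per gene, for 14125 genes. The authors' genome build was GRCm38, and R 3.6.1 and DESeq2 1.24.0 were used, per the submitters' processing notes. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. A second deposited table holds normalized values (a signal per gene). On checking, each of its values was the raw count divided by a DESeq2 size factor, so it added no measurement and was not tested. The smallest summed count of a listed gene was 144 over the 48 libraries, a mean of 3 per library, so genes with fewer counts were not analysed here.

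In 47 of the 48 libraries every deposited count was an even number. In library p13 of the vehicle mice on atglistatin, 49.6% of the values were odd. The cause is not given in the sources used here. The counts were tested as deposited, since the quasi-likelihood test estimates extra variance from the replicates, and the same tests on halved counts were added after the data were examined. Total counts ranged from 10453888 to 24034481 per library, so a gene at 1 CPM rested on about 10 counts in the shallowest library and about 24 in the deepest. The labels name no molecular identifiers, so counts of reads are not counts of independent molecules.

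The groups are called by their label names. EtOH_CON is vehicle with control diet (n = 10), EtOH_ATGLi is vehicle with atglistatin (n = 10), Cort_CON is corticosterone with control diet (n = 14) and Cort_ATGLi is corticosterone with atglistatin (n = 14). Replicates carry the numbers of the sample titles (p01 and so on). The labels give a disease state, diabetic for 9 of the Cort_CON mice and nondiabetic for the other mice, and fed glucose and insulin per mouse without units. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom among 272 pairs was 3.94.

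Genes were kept by edgeR's filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 12592 genes and removed 1533. Library sizes were scaled by TMM. The main test was edgeR 4.0.16's quasi-likelihood test with robust estimation, in R 4.3.3, with all 48 libraries in 1 fit of the 4 groups, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. In the text, "adjusted p" of a gene is this value unless another tool is named, log2 fold changes carry the standard error (SE) derived from the test, and CPM (counts scaled to a common library total) is given as mean ± SD computed from the deposited counts. Contrasts were corticosterone against vehicle on each diet, atglistatin against control diet in vehicle and in corticosterone mice, the interaction of both, and, in a fit with Cort_CON split by disease state, diabetic against nondiabetic.

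Before the data were examined, 33 gene lists (22 pathways or gene families, 11 cell types a muscle sample can hold) were fixed and tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation is given beside it. The lymphocyte list had 1 measured member, Ighm, and its list test is that of a single gene. Named genes followed a rule fixed at the same time: per pairwise comparison the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean of at least 5 CPM and an established symbol, 10 genes named in every comparison (Fkbp5, Tsc22d3, Fbxo32, Trim63, Mstn, Pdk4, Pnpla2, Plin2, Angptl4 and Glul), and the 2 members with the smallest p of each list that passed camera or had at least 25% of its members called. For the interaction and for disease state it was 5 genes each way and the 10. Other list members and genes are named as examples chosen after their values were seen, and some genes the rule picked are not reported here. Of the named genes, 19 overlap another counted gene on the other strand (Glul, Plin4, G0s2, Dbp, Rps28 and Sqstm1 among them) and 4 on the same strand (Per3, Ptprc, Psmd1 and Ndufc2), so their reads could be shared with the neighbour. Close paralogs are uncertain in the same way: Mt1 and Mt2, Amd1 and Amd2, Hba-a1 and Hba-a2, the H2 class II genes, and Klk1b26. Symbols came from a reference table, in which 31 identifiers had no symbol. Gene coordinates are those of a GENCODE annotation of GRCm38.

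Correlations of log2 fold changes between contrasts are across genes, which are not independent replicates, and carry no p. Where 2 contrasts shared libraries, 20 simulated data sets without effects gave the value expected from sharing, and the shared libraries were split at random into separate parts in 20 seeded splits. Glucose and insulin were compared by two-sided permutation tests of the difference of means with 100000 resamples, adjusted over 8 tests.

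The tests were tried on simulated counts drawn from the real means, spreads and library sizes, with 200 of 12592 genes changed. For Cort_CON against EtOH_CON the main test recovered 71.6% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold. For EtOH_ATGLi against EtOH_CON these shares were 65.7%, 79.1% and 97.0%, and for diabetic against nondiabetic mice 50.7%, 77.6% and 92.4%. The share of false calls among all calls was 4.55%, 3.59% and 2.00% in these simulations.

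Other processing choices tried were DESeq2 size factors in edgeR, no filter, a stricter filter (5 CPM in 10 libraries, 5 for disease state), DESeq2 1.42.0, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, fits of the compared groups alone, Cort_CON restricted to its nondiabetic or its diabetic mice, a replicate block on the shared title numbers, and leaving out each nondiabetic mouse. Halved counts, leaving out each other library, leaving out the least correlated library of each group, and leaving out p32, p33 and p34 of Cort_CON, which stood apart together in several named genes, were added after the data were examined. For each comparison, 100 splits of the same libraries, the real one included, were fitted.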

Results

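The series compared gastrocnemius muscle of mice given corticosterone or vehicle in the drinking water, on a control diet or on a diet with the ATGL inhibitor atglistatin. Gene expression was measured by 3′ end sequencing in 48 mice: 10 EtOH_CON, 10 EtOH_ATGLi, 14 Cort_CON and 14 Cort_ATGLi. Total counts per library ran from 12259500 to 20316002 in EtOH_CON, 10453888 to 24034481 in EtOH_ATGLi, 10585234 to 22921262 in Cort_CON and 11283326 to 18743702 in Cort_ATGLi. Each library carries its own glucose and insulin value and was taken as 1 mouse, so the p-values measure the spread between mice under that reading. On the first principal component, with 28.3% of the variance, every vehicle library lay below every corticosterone library. Library p01 of EtOH_CON and p41 of Cort_ATGLi correlated least with the other libraries of their own groups.

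Corticosterone raised fed glucose on the control diet and raised insulin on both diets. Fed glucose was 132.4 ± 10.9 (SD, n = 10) in EtOH_CON and 243.6 ± 79.9 (SD, n = 14) in Cort_CON, in the unit of the labels, which is not stated (permutation test, p = 0.00023, adjusted p = 0.00061). In Cort_ATGLi fed glucose was 114.9 ± 14.8 (SD, n = 14), lower than in Cort_CON (permutation test, p = 1e-05, the smallest the resamples can give, adjusted p = 4e-05), and its difference from the 120.9 ± 16.5 (SD, n = 10) of EtOH_ATGLi did not pass the test (permutation test, p = 0.37). Insulin was 2.42 ± 0.71 (SD, n = 10) in EtOH_CON and 31.7 ± 10.6 (SD, n = 14) in Cort_CON, with no overlap (permutation test, p = 1e-05, adjusted p = 4e-05). Of the 14 Cort_CON insulin values, 9 lay between 36.7 and 39.8, and the others ranged down to 9.31. An upper limit of the assay is not given in the sources used here; with one at that level, the Cort_CON mean and its differences from the other groups would be underestimates. On atglistatin, insulin was 1.17 ± 0.51 (SD, n = 10) in vehicle mice and 17.8 ± 11.7 (SD, n = 14) in corticosterone mice, again without overlap (permutation test, p = 0.00034, adjusted p = 0.00066). Within each water treatment, insulin was lower on atglistatin than on the control diet, at permutation p = 0.00041 (adjusted p = 0.00066) in vehicle mice and p = 0.0042 (adjusted p = 0.0056) in corticosterone mice. The fall of fed glucose from EtOH_CON to EtOH_ATGLi did not pass (permutation test, p = 0.084, adjusted p = 0.096).

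**Figure D1:**
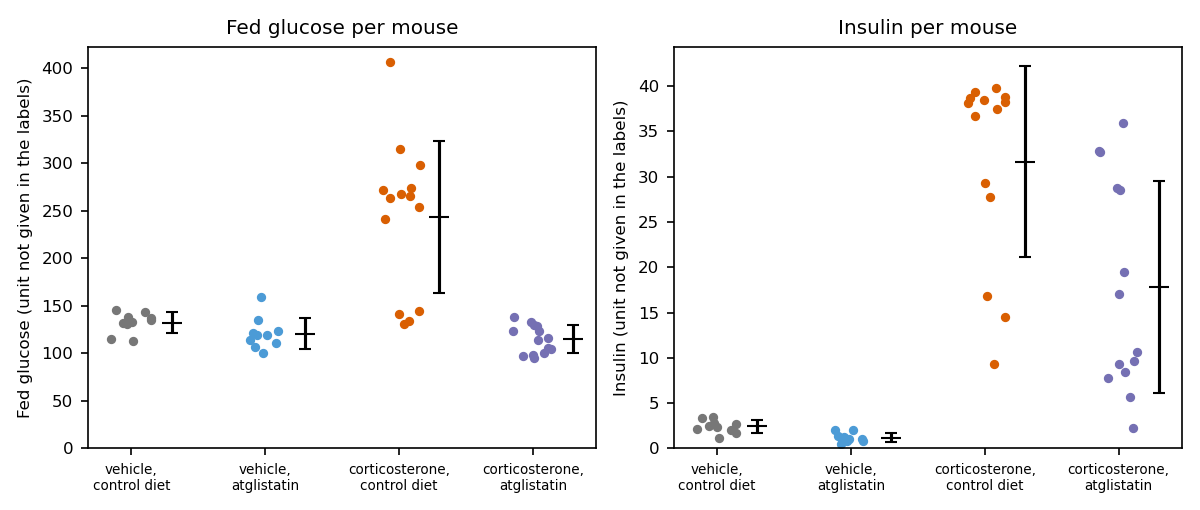
Fed glucose (left) and insulin (right) of each mouse in the unit of the labels, which is not stated, by group; points are mice, and the horizontal marks and bars are means ± SD. Cort_CON glucose spreads from 131 to 407, whereas Cort_ATGLi glucose stays between 95 and 138.

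Corticosterone on the control diet (Cort_CON against EtOH_CON) raised known glucocorticoid receptor targets and lowered extracellular matrix genes. Fkbp5, a co-chaperone of the glucocorticoid receptor on chromosome 17 (28399094 to 28517527), went from 28.7 ± 6.97 CPM (SD, n = 10) to 332.4 ± 75.5 CPM (SD, n = 14), a log2 fold change of 3.53 (SE 0.16, adjusted p = 3.92e-23). The largest rise among genes with a mean of at least 5 CPM in the 2 groups was that of Lcn2, which encodes the secreted protein lipocalin 2 (chromosome 2, 32384633 to 32388252), from 0.93 ± 0.31 to 81.0 ± 43.4 CPM (SD, n = 10 and 14; log2 fold change 6.43, SE 0.40, adjusted p = 1.8e-17). Klk1b26, Pnmt (which makes adrenaline from noradrenaline), the metallothionein Mt2, the glycine methyltransferase Gnmt and the cell cycle inhibitor Cdkn1a followed, with log2 fold changes of 5.38, 5.34, 4.45, 4.27 and 4.11. At the other end of these genes stood the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 and their partner Cd74, with log2 fold changes of -4.11, -3.96, -3.89 and -3.82, the cartilage matrix gene Cilp2 (-3.77) and the collagen gene Col1a1 (-3.62). For all these genes, 14 of 14 Cort_CON libraries lay beyond the EtOH_CON mean CPM in the direction given. Klk1b26 was near the floor in EtOH_CON, at log2 CPM from -2.905 to 0.309, and its rise was 5.24 to 5.74 with 1 library left out. In all, 4838 of 12592 genes passed the threshold, 2384 higher and 2454 lower, and 941 of them changed at least 2-fold.

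Of 27 measured glucocorticoid receptor targets, 23 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 4.93e-25, and adjusted p = 0.0129 with an estimated correlation). Among these targets, Foxo1, a transcription factor of the fasting and atrophy response, rose by 2.91 (SE 0.17) on the log2 scale, Glul, glutamine synthetase, by 2.37 (SE 0.17), and Tsc22d3 by 0.76 (SE 0.09). The atrophy list had 9 of 23 members higher and 2 lower (camera adjusted p = 6.73e-03, but adjusted p = 0.166 with an estimated correlation). It included the muscle ubiquitin ligases Trim63 (1.97, SE 0.24) and Fbxo32 (1.03, SE 0.17), with Cblb (1.07) and Trim54 (0.74). Myostatin, Mstn, a brake on muscle growth, rose by 0.63 (SE 0.14, adjusted p = 2.25e-04). In the proteasome list 14 of 33 members rose and 1 fell (camera adjusted p = 0.020, and adjusted p = 0.592 with an estimated correlation), with Psmc5 at 0.41 and Psmb3 at 0.35. In the autophagy and lysosome list 10 of 24 rose and 2 fell (camera adjusted p = 0.0297, and adjusted p = 0.243 with an estimated correlation), with Map1lc3a at 1.19 and Bnip3 at 0.56.

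Genes of lipid use also moved. Of 31 fatty acid oxidation genes, 19 rose and 2 fell (camera adjusted p = 4.46e-05, and adjusted p = 0.324 with an estimated correlation). Pdk4, the kinase that shuts pyruvate dehydrogenase, rose by 2.75 (SE 0.42), Angptl4, an inhibitor of lipoprotein lipase, by 2.18 (SE 0.39), the fatty acid transporter Cd36 by 0.86 (SE 0.09) and Crat by 0.40. Of 20 lipid droplet genes, 11 rose and 2 fell (camera adjusted p = 1.76e-04, and adjusted p = 0.0634 with an estimated correlation). Pnpla2, which encodes the target of atglistatin (chromosome 7, 141455198 to 141460743), went from 154.4 ± 22.3 to 321.3 ± 132.6 CPM (SD, n = 10 and 14; log2 fold change 1.06, SE 0.16, adjusted p = 2.53e-07). Its inhibitor G0s2 rose by 2.51 and the lipid droplet coat gene Plin4 by 2.17, while Plin2 fell by 0.44 (SE 0.14, adjusted p = 0.011). The glycolysis and glycogen list had 5 of 28 higher and 10 lower (camera adjusted p = 0.728), with the glycogen-targeting phosphatase subunit Ppp1r3c at 2.54. In the insulin, IGF and mTOR list 12 of 28 rose and 4 fell (camera adjusted p = 0.238). Pik3r1, the regulatory subunit of PI3 kinase, rose by 3.30 and Irs1, an insulin receptor substrate, fell by 1.61.

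Of 75 cytosolic ribosomal protein genes 66 rose and 0 fell, 69 adjusted over the list alone, with a median log2 fold change of 0.32 (camera adjusted p = 3.14e-13, and adjusted p = 0.403 with an estimated correlation). Rps28 (0.54) and Rps27 (0.64) had the smallest p. Of 14 slow fibre genes 7 rose (camera adjusted p = 3.02e-03, and adjusted p = 0.403 with an estimated correlation), led by Ankrd2 (1.73) and Myoz2 (1.39). The fast fibre list had 5 of 15 higher and 4 lower (camera adjusted p = 0.154), with Actn3 at 1.03 and Myl1 at -1.14. Of 61 oxidative phosphorylation genes 4 rose and 1 fell (camera adjusted p = 0.44), and of 8 mitochondrially encoded genes 4 rose (camera adjusted p = 0.0844), with mt-Nd6 at 1.23. The circadian clock list had 6 of 18 higher and 6 lower (camera adjusted p = 0.762). In it Dbp fell by 3.02 (SE 0.18). Adjusted over the list alone, 20 fatty acid oxidation genes rose and 2 fell, 11 lipid droplet genes rose and 3 fell, and the counts of the atrophy, proteasome, autophagy and slow fibre lists were the same as over all genes.

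The remaining pathway lists did not pass camera. Inflammation genes had 4 of 12 higher and 4 lower (camera adjusted p = 0.888), with the interleukin 6 receptor gene Il6ra at 2.69 and Relb at -1.16. The integrated stress response list had 3 of 17 higher and 5 lower (camera adjusted p = 0.715), with Ddit3 at -0.81. Neuromuscular junction and denervation genes had 6 of 16 higher and 2 lower (camera adjusted p = 0.109), with Dok7 at 0.80 and Chrnb1 at 0.70. Lipid and cholesterol synthesis genes had 6 of 21 higher and 8 lower (camera adjusted p = 0.894), with Hmgcs1 at -0.34. Polyamine genes had 2 of 11 higher and 4 lower (camera adjusted p = 0.235), with Amd1 at -1.41 and Azin1 at -0.67. Branched-chain amino acid catabolism genes had 2 of 19 higher and 1 lower (camera adjusted p = 0.667).

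The extracellular matrix list had 25 of 27 members lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 2.03e-29, and adjusted p = 0.0111 with an estimated correlation). Col1a1 (chromosome 11, 94936224 to 94953042) went from 238.4 ± 81.6 to 19.3 ± 8.82 CPM (SD, n = 10 and 14), Col6a1 fell by 2.04 (SE 0.14) and the fibrillin gene Fbn1 by 1.88 (SE 0.13) on the log2 scale. Markers of connective tissue cells moved with it. Of 10 fibro-adipogenic progenitor markers 9 fell (camera adjusted p = 4.64e-10, and adjusted p = 0.0132 with an estimated correlation), Smoc2 by 1.15 and Cd34 by 1.04, and of 7 tendon markers 5 fell and 1 rose (camera adjusted p = 1.76e-04, and adjusted p = 0.0634 with an estimated correlation), Tnmd by 2.86. Of 25 interferon and antigen-presentation genes 14 fell and 0 rose (camera adjusted p = 2.04e-07, and adjusted p = 0.083 with an estimated correlation). H2-Aa (chromosome 17, 34282744 to 34287823) went from 48.4 ± 10.9 to 2.78 ± 1.39 CPM (SD, n = 10 and 14). Of 12 macrophage markers 6 fell and 1 rose, with a median log2 fold change of -0.40 (camera adjusted p = 0.0844), among them Ptprc (-1.72) and Csf1r (-0.61). Endothelial markers had 6 of 10 lower (camera adjusted p = 0.020, and adjusted p = 0.403 with an estimated correlation), with Kdr at -0.72 and Tek at -0.86. Among 9 adipocyte markers 4 fell and 1 rose (camera adjusted p = 0.715): Cfd fell by 2.12 (SE 0.34) and leptin, Lep, rose by 2.03 (SE 0.30). Ighm, the immunoglobulin heavy chain gene of B cells, fell by 2.02 (SE 0.39). Its log2 CPM was 5.43, 5.33 and 5.44 in p32, p33 and p34 of Cort_CON and lower in the other 11 libraries; without these 3, picked after their values were seen, the fall was 3.15 (SE 0.33). Neutrophil markers had 2 of 3 lower, Mmp9 (-2.11) and S100a9 (-1.71), with camera adjusted p = 0.0844. S100a9 was near the floor, at log2 CPM from -2.905 to 1.82 in the 48 libraries, and at -2.05 to -1.23 with 1 library left out. Erythroid markers had 4 of 5 higher, among them Hba-a2 (0.52) and Hbb-bs (0.59), also with camera adjusted p = 0.0844. Satellite cell markers had 2 of 5 higher and 2 lower (camera adjusted p = 0.667), with Cdh15 at 0.83 and Sdc4 at 1.01. Schwann cell markers had 2 of 8 lower, with Prx at -0.70 (adjusted p = 0.0448, and 0.126 with limma voom), and smooth muscle and pericyte markers 5 of 8 lower, with Pdgfrb at -0.60 (camera adjusted p = 0.235 and 0.109). Prx missed the threshold (adjusted p up to 0.228) without p10, p11, p15 or p16 of EtOH_CON, or without p27, p28, p29, p30, p32, p34, p35, p45 or p46 of Cort_CON, and was at -0.43 without p15. Adjusted over the list alone, 6 tendon and 7 endothelial markers fell. With only the 5 nondiabetic Cort_CON mice against EtOH_CON, 2856 genes passed, of which 2766 also passed, in the same direction, with all 14.

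**Figure D2:**
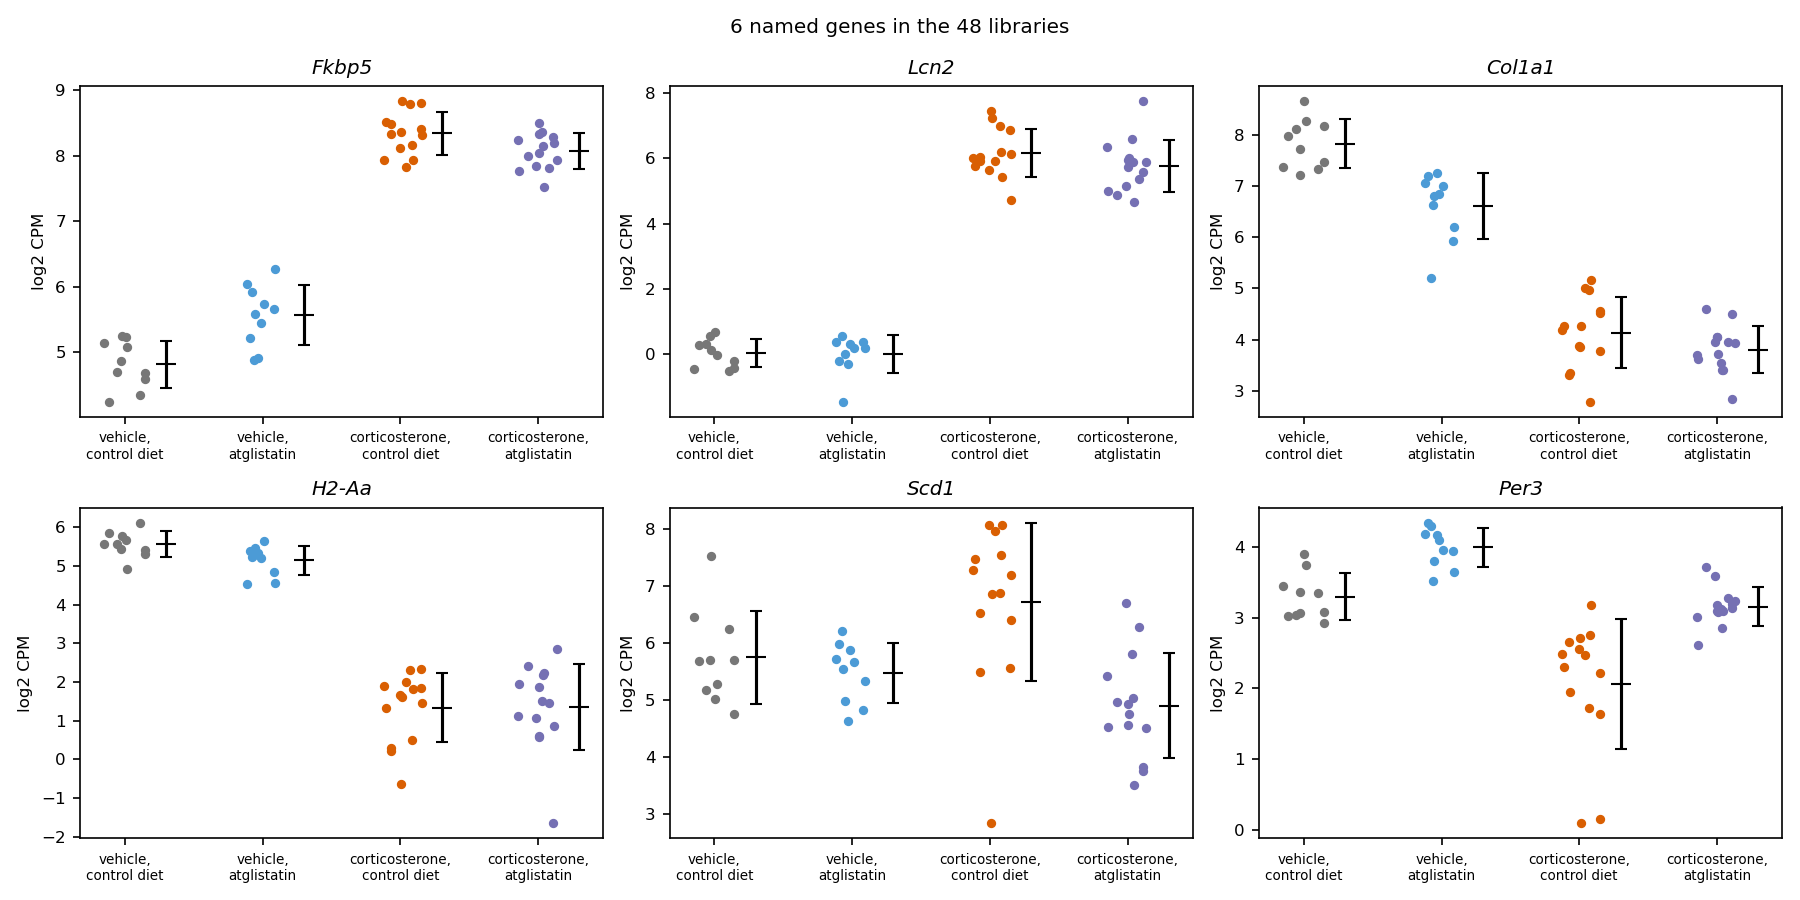
Log2 CPM of 6 named genes in each of the 48 libraries by group; points are libraries, and the horizontal marks and bars are means ± SD of the log2 values. Fkbp5 and Lcn2 are higher and Col1a1 and H2-Aa lower in the corticosterone groups, and Scd1 is lower and Per3 higher in Cort_ATGLi than in Cort_CON.

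On the atglistatin diet, corticosterone (Cort_ATGLi against EtOH_ATGLi) changed 3781 genes, 1887 higher and 1894 lower, 646 of them at least 2-fold. Above a mean of 5 CPM, Lcn2 again had the largest rise (6.13, SE 0.40, adjusted p = 2.94e-16), followed by Mt2 (4.49), Pnmt (4.34), Klk1b26 (4.23), Mt1 (3.88) and the chemokine gene Cxcl13 (3.31). Library p41 of Cort_ATGLi had log2 CPM of 11.88, 11.82 and 5.55 for Mt2, Mt1 and Cxcl13, where the next highest had 9.48, 9.33 and 3.20, and without it the rises were 3.79 (SE 0.37), 3.25 (SE 0.28) and 2.71 (SE 0.39). H2-Aa went from 36.5 ± 8.81 to 3.02 ± 1.83 CPM (SD, n = 10 and 14, adjusted p = 8.34e-15), and H2-Eb1, Cd74 and H2-Ab1 fell by 3.59, 3.58 and 3.51, Ighm by 3.39 and Cilp2 by 3.15 on the log2 scale. For all 12, 14 of 14 Cort_ATGLi libraries lay beyond the EtOH_ATGLi mean CPM in the direction given. Fkbp5 rose from 49.4 ± 15.5 to 272.8 ± 50.2 CPM (SD, n = 10 and 14; log2 fold change 2.47, SE 0.15, adjusted p = 5.16e-18). The glucocorticoid receptor targets had 23 of 27 higher and 1 lower (camera adjusted p = 6.73e-21, and adjusted p = 0.0277 with an estimated correlation). Extracellular matrix genes had 19 of 27 lower and 2 higher (camera adjusted p = 1.95e-20, and adjusted p = 0.0294 with an estimated correlation), with Col1a2 at -2.57 and Col15a1 at -2.47. Fibro-adipogenic markers had 9 of 10 lower (camera adjusted p = 2.9e-10, and adjusted p = 0.0277 with an estimated correlation) and tendon markers 6 of 7 lower (camera adjusted p = 3.06e-05, and adjusted p = 0.0393 with an estimated correlation), with Lum at -1.57 and Thbs4 at -1.44.

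Adjusted over the list alone, 20 extracellular matrix and 15 antigen-presentation genes fell, and 18 proteasome, 15 fatty acid oxidation, 10 slow fibre and 66 ribosomal protein genes rose. The other lists of this comparison that passed camera lost the call with an estimated correlation, the list with Ighm alone included (camera adjusted p = 0.0259, and adjusted p = 0.0735 with an estimated correlation). Trim63 (1.88), Fbxo32 (1.21), Fbxo31 (0.61) and Ubb (0.56) stood among 11 of 23 atrophy genes that rose (camera adjusted p = 1.64e-03, and adjusted p = 0.0771 with an estimated correlation). Proteasome genes had 16 of 33 higher (camera adjusted p = 3.18e-04, and adjusted p = 0.421 with an estimated correlation), with Psmd8 at 0.88. Slow fibre genes had 7 of 14 higher (camera adjusted p = 5.16e-05, and adjusted p = 0.269 with an estimated correlation), and ribosomal protein genes 58 of 75 (camera adjusted p = 1.2e-13, and adjusted p = 0.419 with an estimated correlation). Autophagy genes had 11 of 24 higher, among them Map1lc3a (0.96) and Tfeb (0.69), with camera adjusted p = 2.08e-03 and adjusted p = 0.0735 with an estimated correlation. Fatty acid oxidation genes had 13 of 31 higher (camera adjusted p = 4.65e-04, and adjusted p = 0.419 with an estimated correlation), with Pdk4 at 1.49 (SE 0.39). Lipid droplet genes had 9 of 20 higher (camera adjusted p = 4.65e-04, and adjusted p = 0.0735 with an estimated correlation), with Plin3 at 0.90 and Pnpla2 at 0.96 (SE 0.16). Antigen-presentation genes had 14 of 25 lower and 3 higher (camera adjusted p = 8.11e-05, and adjusted p = 0.23 with an estimated correlation). Glul, Angptl4, Mstn and Tsc22d3 rose by 1.57, 1.97, 0.55 and 0.58 on the log2 scale, and Plin2 (-0.22, adjusted p = 0.262) did not pass, though it did with limma voom (-0.38, adjusted p = 3.86e-03).

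The corticosterone responses on the 2 diets, which share no library, were compared gene by gene. Across the 12592 genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.892 and Spearman's rho = 0.823. Higher on both diets were 1555 genes, where independent lists would share 357, and lower on both were 1538, where independent lists would share 369. No gene was higher on one diet and lower on the other past the threshold in both. The slope of the atglistatin-diet response on the control-diet response was 0.759. Noise in the control-diet values lowers such a least-squares slope even where the responses are equal, so it does not measure their ratio.

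**Figure D3:**
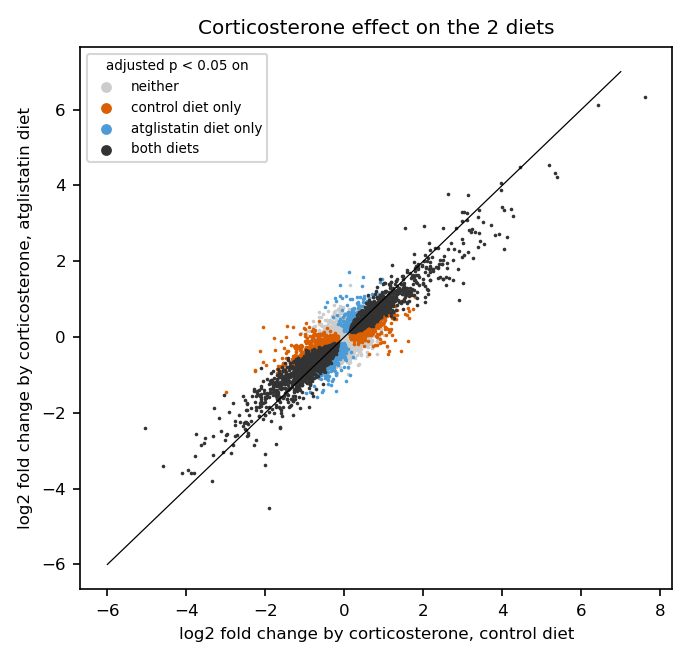
Log2 fold change by corticosterone on the control diet (x axis) and on the atglistatin diet (y axis) for the 12592 tested genes, coloured by where the adjusted p was below 0.05; the line marks equal change. Points follow the line with a lower least-squares slope (0.759), which noise in the x values also lowers.

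Atglistatin in vehicle mice (EtOH_ATGLi against EtOH_CON) changed 3 genes past the threshold. Fkbp5 rose from 28.7 ± 6.97 to 49.4 ± 15.5 CPM (SD, n = 10 each; log2 fold change 0.78, SE 0.15, adjusted p = 0.0219), Mepce, which caps the small nuclear RNA 7SK, rose by 0.41 (SE 0.08, adjusted p = 0.0219), and Sparc, a collagen-binding matrix protein (chromosome 11, 55394500 to 55423183), fell from 353.6 ± 63.7 to 224.9 ± 35.7 CPM (SD, n = 10 each; log2 fold change -0.65, SE 0.10, adjusted p = 3.29e-04). For each, 10 of 10 EtOH_ATGLi libraries lay beyond the EtOH_CON mean CPM in that direction. Single libraries of the 2 groups still overlapped for Fkbp5 and Sparc. Sparc was the 1 member of the extracellular matrix list past the threshold over all genes, and 17 of 27 members fell when adjusted over the list alone (camera adjusted p = 4.06e-33, and adjusted p = 5.81e-03 with an estimated correlation). Col1a1 was at 105.3 ± 38.1 CPM (SD, n = 10; log2 fold change -1.18, SE 0.24, adjusted p = 0.0514), and passed in 6 of the alternative fits, among them DESeq2 (adjusted p = 2.06e-03) and limma voom (adjusted p = 7.08e-04). In the circadian clock list, 4 of 18 members rose when adjusted over the list alone, among them Per3 (0.69), Dbp (0.51) and Bhlhe40 (0.35), and 0 over all genes (camera adjusted p = 4.32e-03, and adjusted p = 0.0335 with an estimated correlation).

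The other 13 lists that passed camera in vehicle mice did not pass with an estimated correlation, and had medians between -0.35 and 0.15. They included glucocorticoid receptor targets with a median of 0.15 (camera adjusted p = 1.38e-04, and adjusted p = 0.382 with an estimated correlation), lipid and cholesterol synthesis with -0.27 (camera adjusted p = 1.5e-04, and adjusted p = 0.22 with an estimated correlation) and ribosomal proteins with 0.08 (camera adjusted p = 1.46e-06, and adjusted p = 0.598 with an estimated correlation). Fibro-adipogenic markers had a median of -0.19, with 3 of 10 lower adjusted over the list alone (camera adjusted p = 4.91e-04, and adjusted p = 0.22 with an estimated correlation), and tendon markers one of -0.24 (camera adjusted p = 0.0203, and adjusted p = 0.27 with an estimated correlation). Adipocyte (median -0.35, camera adjusted p = 8.77e-03), Schwann cell (median -0.33, camera adjusted p = 0.0289) and macrophage markers (median -0.20, camera adjusted p = 0.0392) had 0 members past the threshold, and adjusted p = 0.382, 0.598 and 0.598 with an estimated correlation. Glul (0.45, adjusted p = 0.55), Pdk4 (0.80, adjusted p = 0.753), Pnpla2 (0.13, adjusted p = 0.947) and Plin2 (-0.34, adjusted p = 0.685) did not pass. The count of 3 depended on the method: DESeq2 called 38 genes and limma voom with quality weights 87, all 3 genes among them. Fkbp5 missed the threshold when only these 2 groups were fitted (adjusted p = 0.0604), and (adjusted p up to 0.121) without p02, p03, p09 or p11 of EtOH_CON, or without p05, p06, p07, p08, p11 or p14 of EtOH_ATGLi, and Mepce (up to 0.0926) without the same libraries except p02, while Sparc passed in each fit. With 1 library left out, the log2 fold change of Fkbp5 stayed between 0.68 and 0.85 and that of Mepce between 0.37 and 0.43.

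In corticosterone mice, atglistatin (Cort_ATGLi against Cort_CON) lowered 5 of 21 genes of the lipid and cholesterol synthesis list. Scd1, stearoyl-CoA desaturase (chromosome 19, 44394455 to 44407879), went from 139.5 ± 83.1 to 36.4 ± 26.5 CPM (SD, n = 14 each; log2 fold change -1.94, SE 0.36, adjusted p = 1.28e-03), and Fasn, fatty acid synthase, fell by 1.19 (SE 0.28, adjusted p = 0.0172). Adjusted over that list alone, 12 members fell (camera adjusted p = 4.03e-10, and adjusted p = 0.0318 with an estimated correlation). The fatty acid elongase Elovl6 fell by 1.67 (SE 0.37, adjusted p = 0.0104), Thrsp by 0.93 and ATP citrate lyase, Acly, by 0.76. When only these 2 groups were fitted, Fasn (adjusted p = 0.0646) and Elovl6 (adjusted p = 0.0552) missed the threshold. Ighm (-2.34, SE 0.42), the phosphatase gene Dupd1 (-1.82, SE 0.29), the insulin receptor adaptor Sh2b2 (-1.22, SE 0.26) and the potassium channel gene Kcnk1 (-1.15, SE 0.28) were also among the 6 largest falls of genes with a mean of at least 5 CPM in these 2 groups, which Elovl6 did not reach. Libraries p32, p33 and p34 of Cort_CON, from the mice with the 3 lowest insulin values of that group (14.5, 9.31 and 16.8), had its 3 highest log2 CPM of Ighm (5.43, 5.33 and 5.44) and Dupd1 (5.54, 5.72 and 5.85) and 3 of its 4 highest of Sh2b2. Without these 3, picked after those levels were seen, Dupd1 was at -1.08 (SE 0.22, adjusted p = 6.53e-03), and Ighm (-1.22, adjusted p = 0.0676), Sh2b2 (-0.85, adjusted p = 0.0832) and Kcnk1 (-0.81, adjusted p = 0.187) no longer passed. Kcnk1 also missed the threshold without p32 alone (adjusted p = 0.0527). Above the same 5 CPM, the largest rises were those of the clock genes Per3, from 4.69 ± 2.20 to 8.92 ± 1.76 CPM (SD, n = 14 each; log2 fold change 0.92, SE 0.18, adjusted p = 1.89e-03), and Dbp (0.81, SE 0.17, adjusted p = 7.39e-03). Tmem100 (0.66, and 0.57 with adjusted p = 0.0804 without the same 3 libraries), the myosin light chain kinase Mylk2 (0.56), the sodium-calcium exchanger Slc8a3 (0.56) and Zcchc24 (0.55) followed.

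Of 18 clock genes, 3 rose (Per3, Dbp and Nr1d2, the last by 0.37) and 2 fell (Nfil3 by 0.68 and Clock by 0.37), and the list as a whole did not pass (camera adjusted p = 0.0608). Glucocorticoid receptor targets had 1 of 27 lower, Cdkn1a (-0.97, SE 0.25, adjusted p = 0.0264, and up to 0.0581 without p23 of Cort_ATGLi or without p32, p33 or p34 of Cort_CON), with a list median of -0.15 (camera adjusted p = 1.51e-03, and adjusted p = 0.523 with an estimated correlation). Fast fibre genes had 1 of 15 lower, the calcium store gene Casq1 (-0.41, SE 0.09; camera adjusted p = 2.48e-04, and adjusted p = 0.291 with an estimated correlation), and lipid droplet genes 1 of 20, Agpat2 (-0.68, SE 0.16; camera adjusted p = 0.0126, and adjusted p = 0.291 with an estimated correlation). Proteasome (median 0.09), autophagy (0.10), oxidative phosphorylation (-0.08) and antigen-presentation (0.13) lists passed camera with 0 members past the threshold, and had adjusted p = 0.515, 0.106, 0.798 and 0.515 with an estimated correlation. Fkbp5 (-0.28, adjusted p = 0.322), Trim63 (-0.03, adjusted p = 0.983), Fbxo32 (0.26, adjusted p = 0.517), Pdk4 (-0.46, adjusted p = 0.645) and Pnpla2 (0.04, adjusted p = 0.957) did not pass. In all 201 genes passed, 84 higher and 117 lower, 23 of them at least 2-fold. Without p32, p33 and p34 of Cort_CON together, 100 genes passed, 80 of them among the 201, and Cdkn1a (adjusted p = 0.196) and Casq1 (adjusted p = 0.0761) did not. The count was 125 without p23 of Cort_ATGLi, 356 without p45 of Cort_CON and 71 when only these 2 groups were fitted. In that last fit Sh2b2, Kcnk1, Tmem100, Slc8a3, Cdkn1a and Casq1 no longer passed either (adjusted p from 0.051 to 0.103). Against only the 9 diabetic Cort_CON mice the count was 34, and against only the 5 nondiabetic ones 122. Among these 5 were p32 and p33, whereas p34 was among the 9, so the 2 counts do not compare disease states alone.

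**Figure D4:**
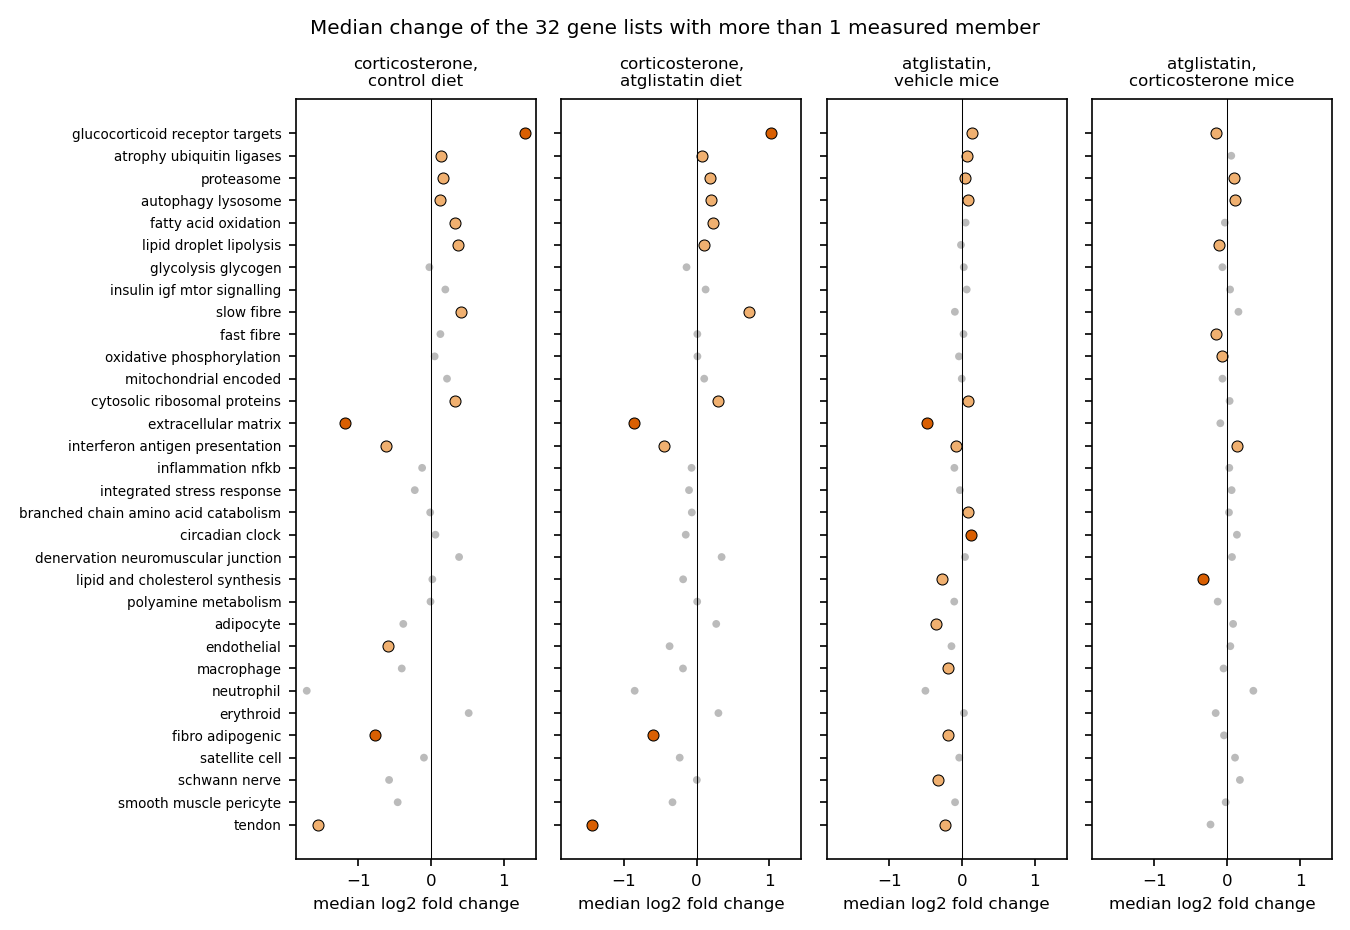
Median log2 fold change (x axis) of the 32 gene lists with more than 1 measured member in the 4 pairwise comparisons; large outlined points passed camera at an adjusted p below 0.05, and dark ones also with an estimated correlation. Extracellular matrix genes lie below 0 with a dark point in the first 3 panels, and lipid and cholesterol synthesis has the one dark point in the last.

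Whether atglistatin moved the corticosterone-responsive genes back was addressed by setting the 2 effects side by side. Of the 201 genes, 69 were lower with atglistatin and higher with corticosterone, where independent lists would share 22.2, and 31 were higher with atglistatin and lower with corticosterone, where independent lists would share 16.4. In the same direction were 13 higher (15.9 for independent lists) and 20 lower (22.8). Both contrasts use the Cort_CON libraries with opposite sign, which gives a negative relation without any effect. Pearson's r across genes was -0.246, and -0.467 in simulated data without effects. The covariance was -0.0323, against -0.0139 in the simulations. With Cort_CON split so that the contrasts shared no library, the median of 20 splits was -0.0207 (r = -0.141, range -0.275 to 0.0271). Without EtOH_CON p01 the median of 20 such splits was -0.0121 (r = -0.0791, range -0.318 to 0.0315). In neither case was r negative in every split.

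The interaction, whether the corticosterone effect differed between diets, passed for 5 genes. For Fkbp5 the effect was smaller on atglistatin, 2.47 against 3.53, a difference of -1.07 (SE 0.20, adjusted p = 0.0121). Sparc fell by 0.63 with corticosterone on the control diet and had a log2 fold change of 0.07 on atglistatin (difference 0.70, SE 0.13, adjusted p = 0.0121), with 228.8 ± 39.4 CPM (SD, n = 14) in Cort_CON and 236.7 ± 25.2 CPM (SD, n = 14) in Cort_ATGLi. Lonrf1 (difference 0.84, SE 0.17) and the integrin gene Itgb5 (0.50, SE 0.10) had adjusted p = 0.0176, and Tmem52 (-0.57, SE 0.12) had adjusted p = 0.0427. Without p32, p33 and p34 of Cort_CON, picked after their values were seen, edgeR's quasi-likelihood test called 0 genes (adjusted p = 0.0555 for each of the 5). The differences were then -0.92 for Fkbp5, 0.62 for Sparc, 0.82 for Lonrf1, 0.45 for Itgb5 and -0.57 for Tmem52. In that fit 658 genes had an unadjusted p below 0.05, where a share of about 0.05 of the 12592 tested would without any effect. Tmem52 missed the threshold in 28 of the 48 fits that left out 1 library (adjusted p up to 0.121), with a difference between -0.62 and -0.51 in all 48. Glul (-0.81, adjusted p = 0.297, and 0.0473 with DESeq2), Pdk4 (-1.26, adjusted p = 0.861), Trim63 (-0.10) and Pnpla2 (-0.10) did not pass. The extracellular matrix list had a median difference of 0.35 (camera adjusted p = 7.82e-15, and adjusted p = 0.297 with an estimated correlation), and glucocorticoid receptor targets one of -0.30 (camera adjusted p = 7.08e-10, and adjusted p = 0.341 with an estimated correlation).

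Among the Cort_CON mice, 9 were labelled diabetic, with fed glucose of 290.9 ± 47.4 (SD, n = 9), and 5 nondiabetic, with 158.6 ± 46.95 (SD, n = 5). Among the nondiabetic mice p36 had a fed glucose of 242 and the other 4 had 131 to 145, and the lowest diabetic value was 254. No gene differed between them past the threshold in edgeR's quasi-likelihood test, DESeq2 or limma voom. In these tests 625, 661 and 830 genes had an unadjusted p below 0.05, where a share of about 0.05 of the 12592 tested would without any difference. Pdk4 (0.58, SE 0.51), Fbxo32 (0.34, SE 0.23), Mstn (0.27, SE 0.18), Angptl4 (0.30, SE 0.47) and Fkbp5 (-0.13, SE 0.19) did not pass. In this comparison 8 lists passed camera, among them ribosomal proteins (median 0.15, camera adjusted p = 3.15e-13, and adjusted p = 0.664 with an estimated correlation), branched-chain amino acid catabolism (median -0.08, with 4 of 19 lower adjusted over the list alone, camera adjusted p = 9.54e-05, and adjusted p = 0.453 with an estimated correlation) and glycolysis (median -0.13, camera adjusted p = 5.7e-04, and adjusted p = 0.453 with an estimated correlation). Of the cell type lists, erythroid markers had a median of 0.34 (camera adjusted p = 1.08e-03, and adjusted p = 0.453 with an estimated correlation) and macrophage markers one of -0.22 (camera adjusted p = 0.0437, and adjusted p = 0.858 with an estimated correlation). None of the 8 passed with an estimated correlation. In fits that left out 1 mouse, 2 genes passed without p29 or p34, 1 without p30 or p49 and 0 without p36. Of the libraries p32, p33 and p34 that stood apart, p32 and p33 were labelled nondiabetic and p34 diabetic. Without all 3, picked after their values were seen, 0 genes passed. Pdk4 was then at 1.02 (SE 0.65), Fbxo32 at 0.47 (SE 0.28), Mstn at 0.39 (SE 0.23), Angptl4 at 0.03 (SE 0.56) and Fkbp5 at 0.07 (SE 0.21).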

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

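The tests of the atglistatin and response-size patterns, and the list of libraries that stand apart, were chosen after the results were seen; the splits of the libraries were planned, and the test of the even counts was set beforehand but read by a rule changed afterwards.

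The corticosterone effect differed between the diets for 5 genes, by the interaction test: Fkbp5 (-1.07 on the log2 scale, atglistatin diet minus control diet), Tmem52 (-0.57), Sparc (0.70), Lonrf1 (0.84) and Itgb5 (0.50). In 1 of 100 splits, the real one, as many genes passed, and the highest of the other splits gave 1. These splits shuffled the diets within each water treatment. That also removes a diet effect common to both, so they do not test the interaction alone. Libraries p32, p33 and p34 of Cort_CON were also left out, picked after their values were seen. The differences were then -0.92 for Fkbp5, -0.57 for Tmem52, 0.62 for Sparc, 0.82 for Lonrf1 and 0.45 for Itgb5. In that fit 0 passed (adjusted p = 0.0555 for each of the 5). By camera with the preset correlation it also differed for glucocorticoid receptor targets (adjusted p = 7.08e-10), extracellular matrix (7.82e-15), fast fibre (3.42e-05), antigen presentation (3.73e-05), Schwann cell (4.94e-03), fatty acid oxidation (0.0192), adipocyte (0.0232) and endothelial (0.0462) lists, and for 0 of them with an estimated correlation.

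A first pattern is that atglistatin alone moved genes in the direction of the corticosterone response: r between the 2 effects was 0.436 across genes. The shared vehicle controls give 0.535 in simulations without effects, but with the controls split between the contrasts r stayed above 0.1 in each of 20 splits (median 0.245, lowest 0.205), and it did so without EtOH_CON p01 (median 0.252, lowest 0.185), which argues against both as the whole cause. Less connective tissue in the EtOH_ATGLi samples is another candidate explanation. With the genes of the connective tissue lists left out, r was 0.236 (lowest 0.194). These lists hold few of the genes tested, so r could hardly change either way and its value decides nothing here. The other values disagree. Genes raised by corticosterone rose 0.037 (median of the splits, range -0.0283 to 0.0803) above the fibre and glycolysis genes. That is within the bound of 0.05 set for this explanation after the pattern had been seen. Without p01 the rise was 0.0585 (range -1.1e-03 to 0.0846), above that bound, so the explanation is left open. Fkbp5 rose by 0.78, but it is 1 of the 3 genes called in this contrast. Its size cannot be set against a median over many genes. An effect of atglistatin or of the mice's own corticosterone stays open and untested.

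A second pattern is the smaller corticosterone response on the atglistatin diet. With genes chosen on 1 part of the control-diet libraries and measured on the other, the response on atglistatin was 0.814 of that on the control diet (median of 20 splits, range 0.759 to 0.897), which argues against the choice of genes as the cause. Measured against the same EtOH_CON mice instead of EtOH_ATGLi, Cort_ATGLi reached 0.964 (range 0.893 to 1.05) of the control-diet response, above the bound of 0.95 in the median but not in each split, so a shifted starting point in the vehicle mice on atglistatin is a candidate explanation. Whether that start is shifted by the drug or by the tissue sampled remains as open as for the first pattern.

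Another pattern is that all counts were even in 47 of 48 libraries, for which the candidate explanation is that each read was counted 2 times. It was predicted that the variance index of low-count genes in the library with odd values, EtOH_ATGLi p13, would then be below that of each other library, and that a value at or above their median would count against it. The value was 3.92, above the median of 3.16, and so met the bound stated against the explanation. That reading was withdrawn after the value was seen, because the other 47 libraries ranged from 2.69 to 21.1: the index sets the spread between single libraries against technical noise, so the test decides nothing. No biological explanation was tested.

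Single libraries of the 2 vehicle groups stood apart in 23 of 300 series tested, against about 1 in 20 by chance, by the gap to the next library divided by the group's range; the corticosterone groups, with 14 libraries each, were not covered by this test. For total counts these were EtOH_ATGLi p13, with 24034481 counts (0.515), and EtOH_CON p15, with 20316002 (0.483). EtOH_CON p01 held 8 of the genes: it was lowest for Map1lc3a (0.631), Sdc4 (0.608), Pik3r1 (0.563), Sqstm1 (0.491), Ptprc (0.486) and Sparc (0.468) and highest for Col15a1 (0.558) and Zcchc24 (0.496). EtOH_CON p10 was highest for Mt2 (0.619), Cyp51 (0.591), Il6ra (0.495), Lep (0.488) and Col6a1 (0.486) and p02 lowest for Itgam (0.563). In EtOH_ATGLi, p09 was lowest for Lcn2 (0.574), Mmp9 (0.497) and Cspg4 (0.468), p14 highest for Hba-a2 (0.570) and Hbb-bs (0.592), p10 highest for Prx (0.508) and p08 highest for Mylk2 (0.571).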

How the results depend on the processing

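Halved counts, fits without single libraries, fits without the least correlated library of each group (EtOH_CON p01, EtOH_ATGLi p05, Cort_CON p45 and Cort_ATGLi p41) and fits without p32, p33 and p34 of Cort_CON were chosen after the data were examined. The counts for corticosterone on the control diet stayed within 1.5 times under 11 of 12 alternatives and fell from 4838 to 2856 with only the 5 nondiabetic mice, which are fewer samples; on atglistatin 9 of 10 alternatives stayed within 1.5 times of 3781. For atglistatin in vehicle mice, 3 genes became 18 with the stricter filter, 38 with DESeq2, 87 with limma voom, 6 with 1 surrogate variable, 39 with only the 2 groups fitted, 19 with halved counts and 5 without the least correlated libraries, and 1 to 21 when 1 library was left out. It was 1 without p03, p09 or p11 of EtOH_CON or p05, p06, p07, p08, p11 or p14 of EtOH_ATGLi, 5 without p01, p12 or p16 of EtOH_CON or p09 of EtOH_ATGLi, 8 without p04 of EtOH_CON, 7 without p13 and 21 without p12 of EtOH_ATGLi. For atglistatin in corticosterone mice, 201 became 375 with limma voom, 399 without the least correlated libraries, 100 without p32, p33 and p34 of Cort_CON, 71 with only the 2 groups fitted, 122 and 34 with only nondiabetic or diabetic Cort_CON mice, and 125 (without Cort_ATGLi p23) to 356 (without Cort_CON p45) with 1 library left out. The interaction count of 5 became 18 with DESeq2, 12 with limma voom, and 8 with 1 surrogate variable and without the least correlated libraries, 0 without p32, p33 and p34 of Cort_CON, and 4 to 7 with 1 library left out. The 0 genes by disease state became 0 to 2 with 1 mouse left out: 2 without p29 or p34, 1 without p30 or p49. The causes were not tested. The correlation of the corticosterone effects was 0.892, and 0.935 with the stricter filter, 0.945 over genes called on the control diet and 0.823 as Spearman's rho. With an estimated correlation, lists past the threshold fell from 13 to 3 and 13 to 4 for corticosterone on the control and atglistatin diets, 15 to 2 and 9 to 2 for atglistatin in vehicle and corticosterone mice, 8 to 0 for the interaction and 8 to 0 for disease state. For atglistatin in corticosterone mice, 1 of these 2 lists was that with Ighm alone (camera adjusted p = 3.53e-03, and adjusted p = 0.0318 with an estimated correlation). Ighm itself missed the threshold there without p32, p33 and p34 of Cort_CON (adjusted p = 0.0676). Glucose and insulin kept their calls on log2 values.

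Of 1504 tests of named genes under alternatives, 1462 kept direction and call, 27 gained and 10 lost the call, and 5 changed sign, none of them called: with limma voom, Trim63 had 0.095 (atglistatin in corticosterone mice), 0.0543 (interaction) and -0.14 (disease state), and Pnpla2 -0.0638 and Angptl4 -0.0265 (disease state). With 1 library left out, 7 of 172 called values of named genes lost the call in at least 1 fit, and without p32, p33 and p34 of Cort_CON 12 of 99 did.

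Title numbers p09 to p14 recur in 2 groups each, and the labels do not say that they pair mice. Deviations of same-numbered libraries correlated between -0.0596 and 0.155, and 1 of 6 libraries correlated best with its own number. With the number as a replicate block in these 12 libraries, 21 genes passed for atglistatin in vehicle mice (3 in the same libraries without the block) and 943 for corticosterone on atglistatin (1458 without the block).

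At these depths and group sizes, 2-fold changes were recovered in 77.6% of simulated genes for disease state and 79.1% for atglistatin in vehicle mice. In 1 of 100 splits, the real one, as many genes passed for corticosterone on the control diet (4838, highest other 616) and on atglistatin (3781, highest other 1561). The same held for atglistatin in vehicle mice (3, highest other 1) and in corticosterone mice (201, highest other 5). That is the smallest share 100 splits can give, so it makes chance unlikely for these counts but cannot exclude it. For atglistatin in vehicle mice, the count was as low as 1 with 1 library left out, no more than in the highest other split. For disease state the observed count was 0, which 100 of 100 splits reach whatever the data (highest other 106), so these splits decide nothing.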

Other observations

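The genes in this part were chosen after their values were seen, apart from the list members. Among genes outside the lists, corticosterone raised Aldh1a1, a retinaldehyde dehydrogenase, by 2.32 on the log2 scale (adjusted p = 1.37e-19), Lrg1 by 2.15 (adjusted p = 5.83e-19) and Syn2, a synaptic vesicle gene, by 3.71 (adjusted p = 3.03e-16) on the control diet. Ccnd1, cyclin D1, fell by 2.50 (adjusted p = 1.81e-17), Cxcl12 by 1.28 (adjusted p = 1.89e-16) and Marcks by 1.95 (adjusted p = 8.77e-20). In corticosterone mice, Cyp1a1, an enzyme induced through the aryl hydrocarbon receptor, was higher on atglistatin (adjusted p = 6.98e-04). Its means of 3.98 against 0.954 CPM both lie below the 5 CPM set for genes named by rule. Prkcd (-1.01, adjusted p = 3.12e-04) and Mybph (-1.01, adjusted p = 2.33e-03) were lower.

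Clock genes in corticosterone mice on atglistatin moved in 2 directions, with Per3 (0.92), Dbp (0.81) and Nr1d2 (0.37) higher and Nfil3 (-0.68) and Clock (-0.37) lower. Arntl (-0.75, adjusted p = 0.057) and Npas2 (-0.73, adjusted p = 0.332) did not pass over all genes. In vehicle mice Per3 (0.69) and Dbp (0.51) passed over the list alone. The labels used here give no time of tissue collection.

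Library p41 of Cort_ATGLi differed from the rest of its group by more than 4-fold in 31 genes upward and 31 downward, of 7623 genes compared. It was higher for the calcium pump regulator Sln (4.71 on the log2 scale), Serpina3n (4.51), Socs3 (3.72), Mt2 (3.46) and Ankrd1 (3.33), and lower for Mss51 (-4.83), Chad (-3.81) and H2-Aa (-3.24). Library p45 of Cort_CON was likewise higher for Sln (3.11) and Ankrd1 (2.14) and lower for Mss51 (-2.70), Scd1 (-4.18) and Ighm (-3.30). Library p01 of EtOH_CON was more than 4-fold lower in 78 genes and higher in 3, with Arhgap5 (-3.94), Usp9x (-3.86) and Vps13a (-3.72) among the lower.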
